A study of Arabidopsis thaliana with 12 samples.

How the data were processed

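The series measured RNA from Arabidopsis thaliana suspension cells with Affymetrix ATH1 arrays, 12 in all, 2 at each of 6 times. The table deposited by the authors holds probe set signal intensities on a linear scale, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. As deposited, the trimmed mean signal of each array was 100.01, so arrays had been scaled to a common level. No detection calls were used, and replicate numbers came from the labels.

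Of 22810 probe sets, 64 Affymetrix controls were left out. Genes came from the platform annotation: 13513 of the other 22746 probe sets had 1 gene, 503 had several and were not named, and 8730 had none listed there, which leaves them unnamed here, not without a gene. Of the 13513, 13436 matched a RefSeq locus tag, giving 13350 genes. A probe set was tested where both arrays of at least 1 day were at or above the array's 40th percentile, which kept 15103 and left out 7643, and 8201 genes were represented. A gene was read from the probe set with the highest mean log2 signal; of 305 genes checked, 0 had another tested probe set of that gene alone.

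The log2 signal was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with 1 mean per day over all 12 arrays and no block, giving 6 residual degrees of freedom and a median of 5.19 prior ones. Tests were 2-sided, with Benjamini-Hochberg adjustment over the 15103 probe sets in each comparison and calls at an adjusted p under 0.05. The median standard error of a difference between days was 0.149. Contrasts were each later day against day 0, each step between neighbouring days, a moderated F over the former, and the alternation (-0.5, 1.5, -2, 2, -1.5 and 0.5 on days 0 to 10, divided by 4), with positive weights on the 27 C days. Simulated data had 200 of 15103 probe sets changed, all on day 6. For day 6 against day 0, 40%, 72%, 100% and 98% of those changed 1.5-, 2-, 4- and 8-fold were called. For day 6 against day 4 these were 46%, 74%, 100% and 100%. At most 12 of 14903 unchanged ones were called in any test. Each percentage rests on 50 probe sets. In the data 62.5% were called for day 6 against day 0, and the adjustment depends on the share changed. The simulated rates therefore do not describe the calls made here.

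A gene with both arrays of a day, or 1 where said, below the 40th percentile of the array has only a bound there. This percentile is a convention used here for signal over background. Each array was raised to it, and the ratio of the geometric means is given as at least that fold, with no fold where both days were dim; in a list's median at the bounds such a gene counts as 0.

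Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over 26 lists and 5 contrasts with day 0 (130 tests); camera with an estimated correlation and fry were run beside it. None of the 26 lists passed on any day with an estimated correlation. The lists fixed in advance numbered 22, with 282 members, of which 36 were named by the annotation and 33 tested. Only 5 lists had the 3 tested members that a test needs: xylan, lignin, vessel cell death, auxin response and heat shock. No member was tested for secondary wall cellulose, brassinosteroid synthesis, ribosome biogenesis, phosphate starvation, nitrate, boron or defence, so those lists gave no result. After the annotation was read, and before any test, 22 lists were added, with 325 members. The annotation named 317 of these members, 225 were tested, and 21 lists were testable. The added lists were drawn from the names the annotation held, except the secondary wall loci. Those were recalled from published compilations, and 18 of their 26 members were named.

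Named genes followed a rule: list members with the largest changes among those passing, plus members going the other way; by log2 change, the 8 largest rises and 5 largest falls on each day against day 0 and the 4 largest each way in each step, among genes whose later arrays both lay beyond both earlier ones; and the 5 largest each way in the alternation among genes with no array below its 40th percentile, a limit added after the largest were seen to be dim. Alternatives were quantile normalization, centring arrays on their medians, no filter or a 60th percentile filter, a pseudocount of 8.50 (the median of the arrays' 25th percentiles), arrays raised to their 40th percentile, no variance trend, the replicate number as a block, the 4 arrays of the days compared alone, no probe sets shared between transcripts, and leaving out each array in turn, where the lone array of that day is assumed to vary like the others.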

Results

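Transcript levels were measured over 10 days in cultured cells of Arabidopsis thaliana, accession Col-0, that were induced to form tracheary elements. These are the water-conducting cells of xylem, which build a patterned, lignified secondary wall and then die. Affymetrix ATH1 arrays were used, on which a gene is read by sets of short probes. The series holds 12 arrays, 2 from untreated cells at day 0 and 2 each from days 2, 4, 6, 8 and 10. Per the labels, 7.5 ml of a 7-day-old culture went into 42.5 ml of fresh medium with 1 uM brassinolide, a brassinosteroid hormone, and 10 mM boric acid. The labels also list a maintenance medium with 2,4-D, a synthetic auxin, which is not among the listed parts of the induction medium. They give 22 C for days 0, 4 and 8 and 27 C for days 2, 6 and 10. Day 0 is the only control. The comparisons with it thus cover the hormone, the boric acid, the change of medium and the age of the culture together. Those of days 2, 6 and 10 also cover a change of labelled temperature, from 22 C to 27 C. Each step between neighbouring days crosses a change of labelled temperature too. All 5 comparisons with day 0 share the same 2 arrays. No label says that the 2 arrays of a day came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. Of the changes of list members against day 0 named here, 111 were checked. In all 111 both later arrays lay beyond both day 0 arrays. Such members were named largely because they passed on these same arrays, so this outcome was favoured in advance and adds no support. The median signal of an array lay between 33.2 and 40.7. The log2 signals of the 2 arrays of a day correlated over probe sets at r between 0.962 and 0.966, day 0 with later days at 0.85 to 0.896, and different later days with each other at 0.904 to 0.967.

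Signals below are means of the 2 arrays of a day, changes are log2 differences ± the standard error of the limma fit, and n is 2 arrays on each side. Where a gene was dim on 1 side, with both arrays, or 1 of them where said, below the 40th percentile of the array, only a bound is given: each array was raised to its 40th percentile before the fold was taken. Genes taken by log2 change rather than from a list were ranked on signals that include those of dim arrays, so dim ones among them are not shown to be the most changed, and their order carries no meaning. Of 15103 probe sets tested, 12199 (80.8%) changed at some time. Against day 0, 5325 rose and 3939 fell on day 2, 5401 and 3890 on day 4, 5215 and 4224 on day 6, 5469 and 4116 on day 8, and 5491 and 4164 on day 10. Between neighbouring days the number that changed was 6770 from day 2 to 4, 2363 from day 4 to 6, 844 from day 6 to 8 and 11 from day 8 to 10. The highest mean fell on day 0 for 3566 probe sets, on day 2 for 3030, on day 4 for 1495, on day 6 for 1460, on day 8 for 739 and on day 10 for 1909. The split between higher and lower depended on the scaling of the arrays. With each array centred on its median, the share of higher calls went from 55.2% to 42.8% on day 6, from 57.1% to 40% on day 8, from 56.9% to 41.4% on day 10, from 49.3% to 38.4% between days 4 and 6, from 53.3% to 28.9% between days 6 and 8, and from 27.3% to 50% between days 8 and 10. It moved the median change of all tested probe sets from 0.10 to -0.02 on day 4, 0.05 to -0.13 on day 6, 0.09 to -0.17 on day 8 and 0.08 to -0.16 on day 10; changes below are relative to the deposited scaling.

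**Figure D1:**
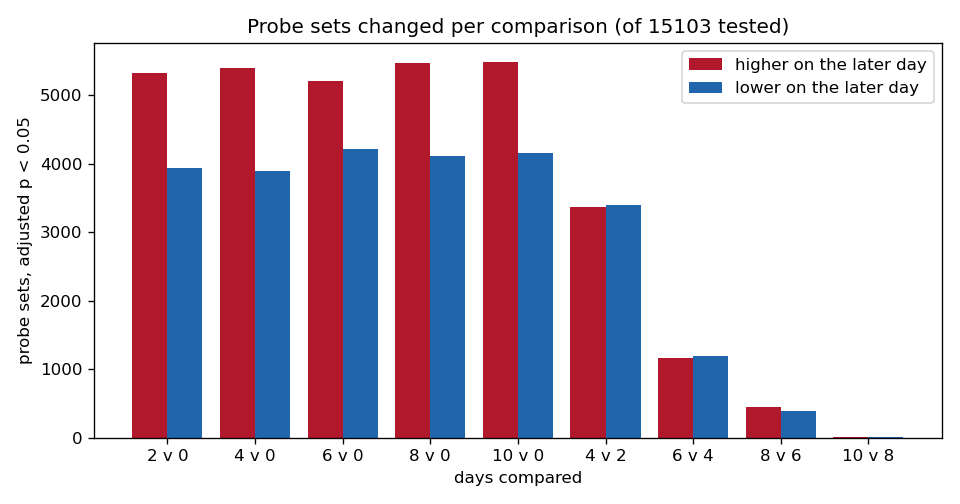
Number of probe sets, of 15103 tested, that were higher (red bars) or lower (blue bars) on the later day at adjusted p under 0.05 in limma, for each pair of days compared. The bars shrink from 6770 in all between days 2 and 4 to 11 between days 8 and 10, and with arrays centred on their medians the lower calls outnumber the higher ones on days 4, 6, 8 and 10 against day 0.

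The comparison of day 2 with day 0 asked what had changed soon after transfer. Most of the measured auxin response genes fell, and most of the measured genes of RNA polymerase I and ribosome biogenesis, several glutathione transferases and the vessel-death protease PASPA3 rose. Of 6 auxin response genes measured, 5 fell and 1 rose, the same counts as adjusted over the list alone. The auxin-conjugating enzymes GH3.5 and GH3.3 fell from 726 to 22.9 (-4.99 ± 0.23) and from 520.0 to 33.4 (-3.97 ± 0.38), and GH3.1 was at least 1.87-fold lower. LBD16, a regulator of lateral root formation, fell by 1.37 ± 0.17 and HAT2 by 0.64 ± 0.18, but HAT2 did not pass without replicate 1 of day 0 (-0.34) or of day 2 (-0.43). IAA29 was the member that rose, from 10.4 to 19.3, at least 1.06-fold; it did not pass when every array was raised to its 40th percentile. As a group the list did not pass (median -2.67, -1.14 with dim genes at their bound, camera adjusted p = 0.125). Of 7 genes of RNA polymerase I and ribosome biogenesis, 6 rose and 1 did not pass, and the list was higher as a group (median 0.84, camera adjusted p = 0.0249; adjusted p = 0.522 with an estimated correlation). YAO, which takes part in making ribosomal RNA, rose from 186 to 517 (1.47 ± 0.09), the exosome subunit RRP41 by 1.21 ± 0.11, and the polymerase I subunits NRPA1 and NRPA2 by 0.92 ± 0.09 and 0.84 ± 0.07. Of 6 tau-class glutathione transferases, which detoxify compounds by conjugation, 4 rose and 1 fell: GSTU22 rose from 27.9 to 1289 (5.54 ± 0.10), GSTU25 from 183 to 1937 (3.41 ± 0.15) and GSTU27 by 1.71 ± 0.17, and GSTU16 was at least 3.62-fold lower. The list did not pass as a group (adjusted p = 0.215).

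On day 2, PASPA3, an aspartic protease of dying xylem cells, had risen from 12.2 to 545, at least 29.9-fold. In its list of vessel cell death genes, 2 of 4 rose, 3 adjusted over the list alone (adjusted p = 0.407). Of 3 heat shock genes, 3 rose, also adjusted over the list alone: the peptidyl-prolyl isomerase ROF2 from 53.1 to 185 (1.79 ± 0.13), the small heat shock protein HSP22 at least 2.29-fold, and HSP15.7 from 32.1 to 66.1 (0.99 ± 0.33), which did not pass without replicate 2 of day 0 (0.89) or of day 2 (0.58). The list did not pass as a group (adjusted p = 0.208). Of 3 lignin genes, 2 rose and 1 fell, PRX66 up and PRX72 down while dim on both days and the fall lost with quantile normalization, and of 3 xylan genes none passed, with the same counts adjusted over the list alone (adjusted p = 0.722 and 0.804). Among 13 genes taken by log2 change, each with both day 2 arrays beyond both day 0 arrays, 8 were dim on day 0 and rose: AT1G28400 at least 17-fold, the peroxidase AT4G30170 at least 18.5-fold, PR-1-LIKE at least 13.2-fold, AT5G66650 at least 6.90-fold, AT4G23670 of the major latex protein family at least 6.63-fold, AT2G40530 at least 4.57-fold, the expansin EXPA8 at least 4.17-fold and AT1G30080 at least 2.84-fold. The 5 that fell were AT5G17340, from 2219 to 7.83 and at least 119.7-fold lower, AT1G08310 at least 50.2-fold, the sugar transporter AT3G05150 at least 18.4-fold, AT3G10720 at least 3.59-fold and AT1G29670 at least 2.80-fold. The highest limma adjusted p among the 13 was 0.00141. At least 2-fold changes numbered 2090 higher and 1695 lower.

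By day 4, limma called every measured gene of the xylan, lignin, vessel cell death and secondary wall lists higher than on day 0, although EXI1, PRX72 and AT3G23090, 1 in each of the last 3 lists, were dim on both days. All 4 vessel cell death genes rose, the same count as adjusted over the list alone. PASPA3 reached 1199.7, at least 65.8-fold above day 0, DMP4 went from 13.8 to 209, at least 11.4-fold, the carboxypeptidase SCPL48 rose from 589 to 1588 (1.43 ± 0.13), and EXI1, dim on both days, has no fold and did not pass without replicate 2 of day 4. The list was higher as a group (median 2.85, 2.47 with dim genes at their bound, camera adjusted p = 0.0366; adjusted p = 0.522 with an estimated correlation). All 16 loci recalled from published compilations as expressed together with secondary wall genes rose (median 3.31, 1.96 with dim genes at their bound, camera adjusted p = 1.09e-05; adjusted p = 0.522 with an estimated correlation). Those compilations may hold arrays from such cultures. The counts, peak days and group tests of these loci, here and on later days, are therefore not independent evidence of their course. AT1G79620, AT1G72230, AT3G52900, AT1G09440 and AT4G08160, which recur below among genes taken by log2 change, belong to these loci. Their rises there are not separate findings. All 3 xylan and all 3 lignin genes rose, also adjusted over each list alone, but neither list passed as a group (adjusted p = 0.164 for each). The xylan genes were IRX10 (1.28 ± 0.16), IRX15 (at least 2.68-fold) and IRX15-L (at least 4.13-fold). The lignin genes were the shikimate transferase HCT (1.36 ± 0.13) and the peroxidases PRX66 (at least 4.60-fold) and PRX72 (dim on both days, so no fold). EXI1 and PRX72 did not pass with arrays raised to their 40th percentile. Auxin response genes kept the day 2 counts of 1 up and 5 down, the same adjusted over the list alone (adjusted p = 0.125). GH3.3 reached its lowest mean, 3.53 against 520.0 on day 0, at least 26.1-fold lower, and IAA29 rose to 88.2 (at least 4.84-fold). Of 3 heat shock genes, 2 rose, also adjusted over the list alone (adjusted p = 0.452).

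Most expansin genes fell between days 2 and 4. Of 9 expansins, 6 fell and 1 rose in this step, and all 3 xyloglucan endotransglucosylase genes fell. Against day 0, EXPA9 went from 647 to 13.1, at least 32.4-fold lower, EXLA1 fell by 2.52 ± 0.16, EXLA2 was at least 1.85-fold lower and XTH19 at least 18.0-fold lower, with XTH18 at least 3.41-fold lower, while EXPA4 rose from 132 to 774 (2.64 ± 0.25). EXPA8 fell back from 76.4 on day 2 to 7.92. Against day 0 on day 4, 3 expansins were up, of which EXPA8 was dim on both days, and 4 down, and 1 xyloglucan gene was up and 2 down; neither list passed as a group (adjusted p = 0.407 and 0.480). Of 12 tubulin and microtubule genes, 9 rose between days 2 and 4 and 8 had their highest mean on day 4. TUB5 rose from 22.7 to 95.2 against day 0 (2.1 ± 0.24) and KINESIN-13A, a kinesin of secondary wall pit formation, by 1.07 ± 0.09; 6 were up and 2 down against day 0 (adjusted p = 0.497). Of the RNA polymerase I and ribosome biogenesis genes, 5 of 7 fell in this step, leaving 4 above day 0, or 1 with arrays centred on their medians (adjusted p = 0.430). The sugar transporter SWEET11 had 26.8 on day 2, 639 on day 4 and 72.7 on day 6, at least 35.0-fold above day 0 on day 4; of 6 SWEET genes 2 were up and 1 down (adjusted p = 0.329). The vacuolar processing enzyme ALPHA-VPE rose from 28.8 to 365 (3.66 ± 0.12) and GAMMA-VPE, down by 0.84 ± 0.08 on day 2, was 0.34 ± 0.08 above day 0; no list test was run on these 2 genes.

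Among 13 genes taken by log2 change on day 4, 8 rose from dim levels: the cupredoxin AT5G26330 at least 55.7-fold, the pectin lyase-like AT1G70500 at least 48.3-fold, AT2G04850 at least 45.2-fold, the receptor kinase AT1G79620 at least 25-fold, AT1G28400 at least 18.6-fold, the thaumatin family gene AT1G20030 at least 8.40-fold, AT4G23670 at least 6.49-fold and the cupredoxin AT1G72230 at least 4.19-fold. The 5 that fell were AT5G17340 at least 111-fold, AT3G13610 of scopoletin synthesis at least 31.0-fold, AT1G23160 of the GH3 family at least 28.9-fold, the glycosyltransferase AT5G05880 at least 20.6-fold and the sugar transporter AT3G05150 at least 17.1-fold. The highest limma adjusted p among the 13 was 7.60e-07. Between days 2 and 4, 3365 probe sets rose and 3405 fell. The 4 rises taken by log2 change, all from dim levels, were AT1G70500 (at least 47.5-fold), the protein kinase AT1G24030 (at least 17.59-fold), AT1G62480 (at least 10.2-fold) and AT1G72230 (at least 4.12-fold). The 4 falls, all to dim levels, were the lipid transfer protein AT5G01870 (at least 52.0-fold), XTH19 (at least 8.75-fold), AT4G14980 (at least 2.62-fold) and AT5G05880 (at least 1.15-fold), the last of which did not pass with arrays raised to their 40th percentile. The highest adjusted p of these 8 was 7.28e-04.

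Day 6 held the highest mean of all 3 xylan genes, all 3 lignin genes, 3 of 4 vessel cell death genes and 15 of 16 secondary wall loci. For the secondary wall loci the limit given for day 4 applies here too. IRX10, a xylan synthase subunit, rose from 51.8 to 495 against day 0 (3.24 ± 0.16), and IRX15 and IRX15-L, needed for normal xylan, from 0.656 to 206 (at least 11.3-fold) and from 4.94 to 380.2 (at least 20.8-fold). HCT rose from 107 to 725 (2.75 ± 0.13), and the peroxidases PRX66 and PRX72 from 6.05 to 509 (at least 28.0-fold) and from 2.50 to 218 (at least 12.0-fold). SCPL48 reached 2935 (2.31 ± 0.13), DMP4 484 (at least 26.4-fold) and EXI1 44.5 (at least 2.40-fold), while PASPA3 was at 487 (at least 26.7-fold). Among the secondary wall loci, the xylanase AT4G08160 was at least 67.1-fold, AT4G27435 at least 54.9-fold, AT1G24600 at least 12.3-fold and the GDSL lipase AT1G54790 at least 22.7-fold higher. All members of these 4 lists rose, as they did adjusted over the list alone for the 3 lists fixed before the data were examined. As groups the vessel cell death list (median 4.19, 3.52 with dim genes at their bound, camera adjusted p = 0.0180) and the secondary wall loci (median 5.65, 4.19 at the bound, adjusted p = 7.68e-08) passed; each had adjusted p = 0.522 with an estimated correlation. The xylan (median 6.75, 3.5 at the bound, adjusted p = 0.0905) and lignin lists (median 6.53, 3.58 at the bound, adjusted p = 0.0676) did not. With 2 lists called in all, 4 were called without replicate 1 of day 0 and 4 without replicate 2 of day 0, the xylan and lignin lists being added each time. The auxin response list stood at 1 up and 5 down, also adjusted over the list alone (adjusted p = 0.164). The heat shock list stood at 1 up, also adjusted over the list alone, or 1 up and 1 down with arrays scaled by quantiles or medians (adjusted p = 0.846).

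**Figure D2:**
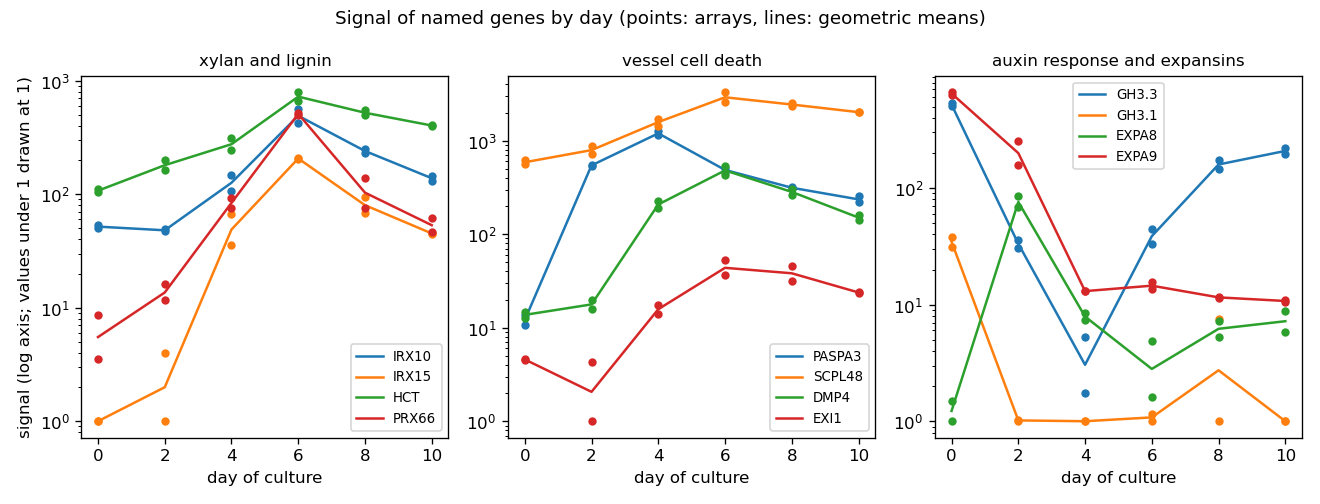
Signal on each array (points, log axis, values under 1 drawn at 1) and geometric mean of the 2 arrays of a day (lines) against day of culture, for 4 xylan and lignin genes, 4 vessel cell death genes, and 4 auxin response and expansin genes. IRX10, IRX15, HCT and PRX66 are highest on day 6, PASPA3 on day 4 and EXPA8 on day 2, and GH3.3 is lowest on day 4 at a mean of 3.53.

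More cell division genes fell than rose by day 6: of 24 measured, 13 fell and 3 rose, or 15 and 1 with arrays centred on their medians. Topoisomerase TOPII fell from 125 to 41.3 (-1.60 ± 0.21), 3xHMG-box2 from 152 to 52.0 (-1.55 ± 0.21) and the histone gene HTB2 from 95.8 to 43.5 (-1.1 ± 0.20), and KINESIN-12B was at least 1.64-fold lower. CDC27a was called higher but was dim on both days, so no fold is given, and Haspin and ATSMC2 rose by 0.33 ± 0.13 and 0.30 ± 0.11. Neither passed with arrays scaled by quantiles or medians, nor Haspin with no filter. Haspin also did not pass without replicate 2 of day 0 or any 1 array of days 6, 8 and 10 (0.25 to 0.34), nor ATSMC2 without replicate 1 of day 0 (0.22) or replicate 2 of day 6 (0.23). The list did not pass as a group (median -0.42, adjusted p = 0.128). Members of the planned replication and mitosis lists were few: the helicase subunit MCM7 fell by 1.01 ± 0.13 and the Aurora kinase AUR1 by 0.82 ± 0.17, the same calls as adjusted over each list alone, and AUR2 went from 26.4 to 32.7 without passing. Of 6 GH9 endoglucanases, 5 rose and none fell, 5 and 1 adjusted over the list alone or with quantile normalization, among them GH9B5 from 21.6 to 88.4 (2.0 ± 0.23), GH9B7 from 481 to 1258 (1.39 ± 0.09) and GH9B17 (at least 1.82-fold); the list had adjusted p = 0.199. Of 8 lignin-related genes named after the annotation was read, 4 rose and 3 fell (adjusted p = 0.687). The peroxidase PRX52 rose from 5.81 to 246 (at least 13.0-fold) and HCT is counted here too, while the monolignol glucosyltransferase UGT72E1 was at least 9.75-fold lower, CYP84A4 at least 2.81-fold lower and CCOAMT fell by 0.79 ± 0.26, not passing without replicate 1 of day 0 (-0.66) or of day 6 (-0.56). Of 12 TBL genes, a family of wall acetyltransferases, 6 rose and 3 fell (adjusted p = 0.479). TBL34 rose from 13.6 to 907 (at least 49.8-fold), TBL36 was at least 7.39-fold higher, and TBL39 fell from 499 to 77.4 (-2.69 ± 0.17) and TBL26 by 0.74 ± 0.19. Tubulin genes had 4 up and 3 down, or 3 and 5 with arrays centred on their medians (median 0.03, turning to -0.15 when centred; adjusted p = 0.959), with TUB5 up by 1.31 ± 0.24 and TUB7 down by 1.02 ± 0.11.

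Among 13 genes taken by log2 change on day 6, 8 rose from dim levels: the protein kinase AT1G24030 at least 104-fold, AT1G70500 at least 95.1-fold, the thaumatin family genes AT5G40020 at least 63.4-fold and AT1G20030 at least 14.4-fold, AT3G52900 at least 20.7-fold, the protein kinase AT1G09440 at least 16.2-fold, AT1G79620 at least 14.9-fold and AT1G28400 at least 13.2-fold. The 5 that fell were AT4G23590 of the tyrosine aminotransferase family at least 39.5-fold, AT3G13610 at least 29.7-fold, AT5G05880 at least 19.7-fold, AT4G14980 at least 17.1-fold and AT3G05150 at least 16.4-fold. The highest limma adjusted p among the 13 was 1.88e-05. Between days 4 and 6, 1164 probe sets rose and 1199 fell. AT4G08160 rose from 70.2 to 1222 (4.27 ± 0.42), the remorin AT5G23750 at least 22.7-fold and AT1G05310 of the pectin methylesterase family at least 7.55-fold, and AT1G48690 was at least 1.35-fold higher. The GDSL lipase AT1G71250 was at least 17.1-fold, AT5G43000 at least 2.65-fold, AT5G38180 at least 1.78-fold and AT1G17830 at least 1.15-fold lower, with a highest adjusted p of 0.00231 among the 8. AT1G48690 and AT1G17830 did not pass with arrays raised to their 40th percentile. In this step 3 of 3 lignin genes, 2 of 3 xylan genes and 10 of 16 secondary wall loci rose further, 2 vessel cell death genes rose and 1 fell, and 6 of 12 tubulin and microtubule genes fell. The 2363 changes became 1289 without replicate 1 of day 4, 1343 without its replicate 2, 1084 without replicate 1 of day 6 and 1457 without its replicate 2.

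On days 8 and 10 the mean signals of the xylan, lignin and cell death genes stood between those of days 6 and 0. IRX10 had 240.1 on day 8 and 138 on day 10, HCT 522 and 402, PRX66 108 and 53.8, DMP4 284 and 151, and PASPA3 314 and 236. All members of the xylan, lignin and vessel cell death lists were above day 0 on both days, also adjusted over each list alone, and so were 16 of 16 and 15 of 16 secondary wall loci, with AT3G23090 dim on days 0 and 8. The cell death list passed on day 8 (median 3.71, 3.01 with dim genes at their bound, camera adjusted p = 0.0249) and day 10 (median 2.92, 2.41 at the bound, adjusted p = 0.0366). So did the secondary wall loci (medians 4.78 and 3.68, 3.1 and 2.04 at the bound, adjusted p = 1.06e-06 and 1.23e-05), and all 4 calls had adjusted p = 0.522 with an estimated correlation. The xylan list had adjusted p = 0.125 and 0.164, and the lignin list 0.123 and 0.128. GH3.3 was back at 159.7 and 208, still below day 0 on day 10 (-1.32 ± 0.38), although not passing without replicate 1 of day 10 (-1.24); of 6 auxin response genes 4 and 3 were down and 1 up, also adjusted over the list alone, or 5 and 5 down with arrays centred on their medians (adjusted p = 0.345 on each day). Of 3 heat shock genes, 1 was up on each day, also adjusted over the list alone, with another down on day 8 when arrays were scaled by quantiles or medians (adjusted p = 0.658 and 0.532). EXPA9 remained low at 10.7 (at least 30.4-fold below day 0), EXPA15 fell by 2.07 ± 0.15 and GSTU26 went from 290.5 to 10.6 (at least 13.6-fold lower).

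Taken by log2 change against day 0, the 8 rises on day 8 were AT1G70500 at least 63.4-fold, AT1G24030 at least 63.0-fold, AT5G40020 at least 37.0-fold, AT1G28400 at least 16.1-fold, AT5G10210 at least 16.1-fold, AT3G10320 at least 9.48-fold, AT1G09440 at least 8.17-fold and AT1G79620 at least 7.94-fold. The 5 falls were AT1G04660 at least 72.4-fold, AT4G23590 at least 37.3-fold, AT3G13610 at least 28.1-fold, AT5G05880 at least 18.6-fold and AT4G14980 at least 16.2-fold, with a highest limma adjusted p of 1.65e-05 among the 13. On day 10 the rises were AT1G62480 at least 44.8-fold, AT1G70500 at least 43.6-fold, AT1G24030 at least 37.1-fold, AT5G10210 at least 29.7-fold, AT4G34600 at least 18.6-fold, the bHLH gene AT1G61660 at least 12.5-fold, AT1G28400 at least 11.9-fold and AT3G10320 at least 9.39-fold. The falls were the lipid transfer protein AT5G01870 at least 178-fold, AT1G04660 at least 75.1-fold, AT4G23590 at least 38.7-fold, AT5G05880 at least 19.3-fold and XTH19 at least 16.8-fold, with a highest adjusted p of 4.95e-05.

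From day 6 to day 8, 450 probe sets rose and 394 fell. Of the lists above, 5 of 16 secondary wall loci, 1 of 3 xylan genes, 1 of 3 lignin genes and 2 of 4 vessel cell death genes fell, the others not passing. The peroxidase gene AT5G51890, which is PRX66, fell from 509 to 108 (-2.30 ± 0.38), but did not pass without either day 6 array or without replicate 1 of day 8 (-2.33, -2.28 and -1.86). The other falls taken by log2 change were AT1G56720 (at least 3.88-fold), AT5G02550 (at least 1.27-fold) and AT2G21510. Called higher were AT5G20790, dim on 1 day 6 array (at least 4.70-fold), the sucrose-phosphate synthase gene ATSPS4F, AT2G04500 and NRPE7, a subunit of RNA polymerase V. AT2G21510, ATSPS4F, AT2G04500 and NRPE7 were dim on both days, so no fold is given. The highest limma adjusted p of these 8 was 0.0466. With arrays raised to their 40th percentile, ATSPS4F, AT2G04500, NRPE7, AT2G21510 and AT5G02550 did not pass, and ATSPS4F, AT2G04500, AT1G56720 and AT2G21510 also did not pass without any 1 of the 4 arrays compared (-2.28 to -1.93 for AT1G56720). NRPE7 did not pass without replicate 2 of day 6 or either day 8 array, nor AT5G02550 without replicate 2 of day 6 (-1.62) or replicate 1 of day 8 (-1.45). Leaving out either array of some other days also ended the call of ATSPS4F (days 0 and 10), AT1G56720 (day 10, -2.1) and AT2G21510 (days 2 and 10). AT1G56720 and AT2G21510 also failed with no filter or without the variance trend, AT2G21510 and ATSPS4F with a pseudocount added, and ATSPS4F with arrays centred on their medians. The 844 changes became 228 without replicate 1 of day 6, 235 without its replicate 2, 211 without replicate 1 of day 8 and 141 without its replicate 2.

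From day 8 to day 10, 3 probe sets rose and 8 fell in limma, with 1296 at an unadjusted p under 0.05. The methionine sulfoxide reductase gene MSRB9 rose by 0.85 ± 0.12, and AT5G06930, the cupredoxin AT5G26330 and AT3G14360 fell by 1.16 ± 0.14, 1.12 ± 0.16 and 0.87 ± 0.13, with a highest adjusted p of 0.0450. AT5G19250 was at least 1.16-fold lower, and AT1G74490 was dim on both days and has no fold. Each of these 6 failed without single arrays: AT1G74490, AT5G19250, AT5G06930, AT5G26330 and AT3G14360 without any 1 of the day 6, 8 or 10 arrays (for the last 4, -1.84 to -1.72, -1.28 to -1.04, -1.20 to -1.04 and -1.02 to -0.73), and MSRB9 without either day 6 array (0.85), either day 8 array (0.83 and 0.86) or replicate 2 of day 10 (0.66). All 6 failed with no filter, all but AT1G74490 without the variance trend, and AT5G19250 and AT3G14360 with arrays centred on their medians. With the replicate number as a block, AT1G74490, AT5G19250 and AT3G14360 failed (adjusted p = 0.0510 each), although the number called was again 11. AT1G74490 and AT5G19250 also failed with arrays raised to their 40th percentile. The count of 11 became 47 and 46 without replicate 1 and 2 of day 0, 28 without either array of day 2, 22 and 23 without those of day 4, 1 without either of day 6, 0 without either of day 8, and 2 and 0 without those of day 10. Over the longer step from day 6 to day 10, chosen after the count for days 8 to 10 was seen, 1615 probe sets rose and 1297 fell. In it 15 of 16 secondary wall loci, 2 of 3 xylan genes, 2 of 3 lignin genes and 3 of 4 vessel cell death genes fell.

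Because the labels alternate between 22 C and 27 C from one time to the next, a contrast that is 0 for any linear or quadratic course gave alternating weights to the days. It called 1805 probe sets, 924 with a positive and 881 with a negative value. A positive value does not mean that each 27 C day was higher than its 22 C neighbours. Each inner day was also set against the mean of its neighbouring days. For 592 of the 1805 these differences alternated with the labels at all 4 inner days. Even then a day need not lie beyond both neighbours. The 5 largest values each way came from genes below the 40th percentile on 6 to 10 of the 12 arrays, so no size is given for them. Among genes with no array below it, a limit set after those values were seen, the largest positive values were those of the isocitrate lyase gene ICL (1.03 ± 0.10 per contrast unit), AT2G41380 (0.98 ± 0.19), AT3G28200 (0.98 ± 0.13), ZW9 (0.85 ± 0.20) and the zinc finger gene STZ (0.80 ± 0.14). The largest negative ones were those of the cation transporter OCT1 (-1.46 ± 0.14), AT3G15450 (-1.23 ± 0.21), AT4G34950 (-1.16 ± 0.06), AT3G15630 (-1.08 ± 0.12) and AT5G48500 (-1.06 ± 0.10), with a highest limma adjusted p of 0.0197. ICL, for example, had 1556, 559, 86.2, 195, 88.3 and 69.6 on days 0 to 10. Of these 10, only ZW9 failed without single arrays, namely replicate 2 of day 2 (0.83), both of day 4, in turn (0.83 and 0.87), replicate 1 of day 6 (0.72) and replicate 1 of day 8 (0.72). The count became 1098 without replicate 1 of day 4 and 978 without replicate 1 of day 6. The heat shock genes were not called as a set in this contrast (camera adjusted p = 0.573, and 0.788 with estimated correlation).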

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

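The contrast of day 10 with day 2, the heat shock test in the alternation, the ratio over the 1805 probe sets called in it and both tests of the late fall were chosen only after the results they concern were seen. A total of 144 genes were higher than day 0 on day 2 and lower on day 10, and 135 were lower and then higher. These counts hold only genes whose difference between the 2 days also passed in limma, so that test adds no support. Of the former, AT2G03980, a GDSL lipase, changed by 2.69 ± 0.46 on day 2 and was at least 1.46-fold lower on day 10, AT5G23840 by 0.81 ± 0.32 and was at least 3.27-fold lower, and AT3G28200 by 0.84 ± 0.20 and -2.28 ± 0.20. AT5G38700 was at least 3.5-fold higher on day 2, but 1 day 0 array and both day 10 arrays were below the 40th percentile and no bound can be given for its fall. Of the latter, AT1G62480, AT1G24030, AT5G40020 and AT5G66390, the peroxidase PRX72, were at least 44.8-fold, at least 37.1-fold, at least 16.6-fold and at least 5.74-fold higher on day 10. All 4 were dim on days 0 and 2, so no fold is given for their day 2 calls, which are differences near background. Of the 135 genes, 19 had all 4 arrays of days 0 and 2 below the 40th percentile and 2 all 4 of days 0 and 10, and of the 144 genes 0 and 0 did. Day 2 and day 10 carry the same temperature label.

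The alternation contrast called 1805 probe sets, and a response of equal size at each change of temperature is 1 candidate explanation. The second difference at a day is its value minus the mean of its neighbouring days, and the day need not lie beyond both. If such a response were the main source of the second difference at day 2, that at day 8 would be its mirror, with a median ratio near 1. Over 7760 probe sets called at day 2 the median ratio was -0.0446 (95% bootstrap interval -0.0487 to -0.0407), 3074 (39.6%) had the opposite sign at day 8, and limma called 0 in the day 8 difference (689 at an unadjusted p under 0.05); over the 1805 the median was -0.00349 (-0.0113 to 0.00486). Of the 1805, whose selection favours agreement at each inner day, 1754 (97.2%) had a second difference that followed the temperature label at day 2. The number was 1727 (95.7%) at day 4, against 978 (54.2%) at day 6 and 900 (49.9%) at day 8, and 592 (32.8%) at all 4. This argues against a response of constant size as the main source of the day 2 differences or of the 1805 calls. The day 2 difference also holds any response to transfer and induction, so a smaller response of constant size cannot be excluded. A response that depends on the stage of the culture stays open too. Whether heat shock genes were higher at 27 C cannot be told apart from no change with so few genes (camera adjusted p = 0.573).

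The 26 xylan, lignin, vessel cell death and secondary wall genes that were up on day 6 all had a lower mean signal above day 0 on day 10 than on day 6, by log2 ratios from -3.42 to -0.71 (median -1.97), and 22 of them passed as lower in limma. Loss of 1 share of the cells that carry these transcripts, with all of their RNA, could give such a course, and would lower each gene by the same factor. The spread of the ratios had an SD of 0.676 (95% bootstrap interval 0.470 to 0.838). It was set against 0.654, 2 times the median limma standard error of a log2 difference between days for these genes. That is not the standard error of the ratios above day 0, so this comparison did not decide the question. The ratios from the replicate 1 arrays and the replicate 2 arrays correlated across 25 of the genes at Pearson r = 0.895 (interval 0.836 to 0.953; Spearman 0.92; permutation p = 1e-05 each, the smallest that 100000 permutations can give; r = 0.883 without the 2 farthest genes), although genes are not independent replicates, so genes differed in this ratio, which argues against a single common factor. The ratios take the day 0 signal as an unchanged background, and the 2 arrays of a day may be technical replicates. Non-linear response of single probe sets and change in the remaining cells stay open and were not tested.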

How the results depend on the processing

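The fifth difference and the day 10 against day 6 step were added after the data were seen. The ranges in the next 2 sentences do not cover the fits of the 4 arrays alone. In the other alternatives, counts against day 0 and the count at any time stayed within 1.5 times of the reported ones. They ran from 7450 on day 4 to 10012 on day 10 for single days, from 9707 to 12515 at any time, and from 5309 to 7038 for day 4 against day 2. The 11 calls from day 8 to 10 became 165 with the 4 arrays alone, 60 with quantile normalization, 0 with no filter (limma), 31 with the 60th percentile filter, 89 with the pseudocount, 148 with arrays raised to their 40th percentile, 1 without the variance trend, 2912 with day 6 in place of day 8 and 0 to 47 leaving out arrays. Day 8 against 6 gave 418 without the trend and 141 to 1029 leaving out arrays, day 6 against 4 gave 1084 to 2551, and the alternation 984 with the fifth difference and 978 to 1983. Lists called on day 6, 2 of 26, were 0 with an estimated correlation, 23 with fry, which tests a list against no change, 4 with median centring, 5 with no filter, 4 with the pseudocount, 4 with raised arrays and 2 to 4 leaving out arrays. With no filter the list of vacuolar processing enzymes also had enough members to be tested. Over the alternatives run with camera, the day 6 adjusted p was 0.0161 to 0.571 for xylan, 0.0104 to 0.522 for lignin, 0.00127 to 0.522 for vessel cell death and 6.25e-11 to 0.522 for the secondary wall loci. Medians of day 6 that changed sign were, with quantile normalization, plastid photosystem -0.0716; with median centring, tubulin -0.15, autophagy -0.14, photosystem -0.16 and plastid NDH -0.0543; with no filter, carboxypeptidases 0.21, monolignol -0.47 and cold -0.28; and with raised arrays, heat shock 0.19 and carboxypeptidases 0.19. On other days the sign changed with quantile normalization for autophagy on day 4 (-0.0233 to 0.0129), TBL on day 8 (0.18 to -0.0212), autophagy on day 10 (-0.0298 to 0.0305) and mitochondrial on day 10 (0.0575 to -0.14), and with median centring for TBL on day 8 (0.18 to -0.0771), autophagy on day 8 (0.0834 to -0.17), TBL on day 10 (0.21 to -0.0217) and mitochondrial on day 10 (0.0575 to -0.18). Leaving out arrays, day 6 medians ranged over -0.41 to 0.20 for heat shock, -0.21 to 0.0979 for expansins, -0.0212 to 0.0721 for tubulin, -0.20 to 0.26 for photosystem, -0.11 to 0.38 for NDH, -0.34 to 0.0420 for mitochondrial and -0.0930 to 0.0297 for exocyst genes. With raised arrays, AT2G21510 (day 8 against 6) was 0.0815 and AT1G74490 (day 10 against 8) -0.0515. These and the list medians of 0.19 are differences between the percentiles of days on which the gene was dim. Of 4508 alternatives for 216 gene values, 4362 kept their side, 144 no longer passed, 0 newly passed and 2 changed sign, and of 597 for the 26 lists on day 6 539, 2, 35 and 21. The cause was not tested, apart from fewer arrays or other probe sets where the setting removes or adds them. Whether equal replicate numbers pair the arrays stays open: the 15 correlations between days of their deviations ran from -0.0671 to 0.128, with 11 positive and 4 above 0.1, and replicate 1 had the higher median signal on 5 of 6 days. The replicate block gave 9448, 9446, 9639, 9761 and 9875 calls on days 2 to 10, 7038, 2575, 978 and 11 in the steps, 1999 in the alternation, 12359 at any time and 2 lists. Signal over background limits dim genes, for which bounds are given.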

Other observations

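The lists described next were added after the annotation was read, except those named as fixed in advance, and no test was chosen after its result was seen. Of 13 serine carboxypeptidase-like genes, 6 rose, 1 of them dim on both days, and 6 fell on day 6 (camera adjusted p = 0.940); scpl20 rose from 33.8 to 452 (3.73 ± 0.19), SCPL45 from 77.9 to 986 on day 4 (3.67 ± 0.13), and scpl35 was at least 9.36-fold lower on day 4. Of 6 cold and dehydration genes, 3 rose and 2 fell on day 6 (adjusted p = 0.452). The dehydrins COR47 and LTI30 rose from 29.8 to 629 (4.41 ± 0.12) and from 15.6 to 164 (at least 8.91-fold), and the osmotin OSM34 fell from 2148 to 115 on day 2 (-4.31 ± 0.23) and was at 1223 on day 6. Of 10 autophagy genes, 5 fell and 1 rose on day 2 and 3 rose and 1 fell on day 6, or 2 and 4 with arrays centred on their medians, when the median was 0.04, or -0.14 when centred (adjusted p = 0.199 and 0.722); ATG8H was at least 8.23-fold higher on day 6 and ATG8E, the member measured of the sugar starvation list fixed in advance, rose from 261 to 442 (0.76 ± 0.11). Of 7 exocyst genes 2 rose and 1 fell on day 6, or 2 and 0 with quantile normalization (adjusted p = 0.953), SEC15A by 1.24 ± 0.16 and SEC10 by -0.27 ± 0.07, the latter not passing with quantile normalization (-0.11) or without replicate 2 of day 6 (-0.22). Of 6 SWEET genes 4 rose and 1 fell (adjusted p = 0.215), with SWEET17 at 2.35 ± 0.09.

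Of 27 photosystem and cytochrome genes of the plastid genome, 9 fell and 2 rose on day 2, or 12 and 1 with arrays centred on their medians, and 11 rose and 5 fell on day 10, or 6 and 7 when centred (adjusted p = 0.125 and 0.480); psbE and psbF fell by 1.38 ± 0.16 and 1.34 ± 0.27 on day 6, when the median of 0.01 turned to -0.16 with arrays centred on their medians and to -0.07 with quantile normalization. Of 10 plastid NDH genes 5 rose and 0 fell on day 8 in limma, or 3 and 0 with arrays centred on their medians, the others not passing (adjusted p = 0.268); ndhJ was at least 3.18-fold higher on day 10, but did not pass without replicate 2 of day 0 (1.35) or replicate 1 of day 10 (1.19). Of 17 plastid polymerase and ribosome genes 10 rose and 1 fell on day 10, or 9 and 3 with arrays centred on their medians, with rps16 up by 1.64 ± 0.22 (adjusted p = 0.164). Of 11 mitochondrial genes 5 rose and 2 fell on day 2, nad4L by 1.56 ± 0.12 and nad4 by -1.53 ± 0.34, and ccb452 fell by 1.3 ± 0.12 on day 6 (adjusted p = 0.722 and 0.455). Of 7 nuclear genes for plastid proteins, 5 rose and 1 fell on day 6 (adjusted p = 0.226). RCA, which activates Rubisco, rose from 35.3 to 247 (2.81 ± 0.14), LHCB4.1 and LHCB4.3 were at least 5.43-fold and at least 7.21-fold higher, and LIL3:1 was at least 1.17-fold lower, although not with arrays raised to their 40th percentile; RCA and LHCB4.1 are the members measured of the photosynthesis list fixed in advance. Of 6 vascular and CLE genes 5 rose and 1 fell on day 10 (adjusted p = 0.164). OPS, the member measured of the phloem list fixed in advance, rose from 14.1 to 172 (at least 9.42-fold), CLE44 fell by 1.56 ± 0.17, and the procambium list fixed in advance had PHV, a class III HD-ZIP gene, up from 112 to 583 (2.38 ± 0.09) and LHW up by 1.19 ± 0.14 on day 6. Of single members measured of other lists fixed in advance, C3H14 was at least 1.52-fold higher on day 6, KINESIN-13A was as given for day 4, EXPA8 as given for day 2, and of the primary wall list CSLC4 rose by 1.19 ± 0.10 and COB fell by 0.24 ± 0.10 on day 6. COB did not pass without either array of days 0 (-0.29 and -0.20), 6 (-0.25 and -0.24) or 10 (-0.24 each), nor with no filter or without the variance trend (adjusted p = 0.0572 and 0.0742).

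Median, mean and camera direction of a list, none of these lists passing as a group, differed in sign on day 2 for TBL (-0.08, 0.23, lower), expansins (0.32, 0.66, lower), xyloglucan (-0.36, 0.04, higher), carboxypeptidases (-0.12, 0.34, higher), SWEET (-0.02, -0.00, higher) and cold (0.13, -0.35, lower). They also did so on day 4 for autophagy (-0.02, 0.25, lower), plastid NDH (-0.07, 0.00, lower), cell division (-0.15, 0.01, lower) and exocyst (-0.03, 0.14, lower). They did so on day 6 for heat shock (-0.10, 0.22, higher), tubulin (0.03, 0.09, lower), plastid photosystem (0.01, -0.02, lower) and exocyst (-0.06, 0.21, higher). They did so on day 8 for exocyst (-0.11, 0.07, lower). They did so on day 10 for autophagy (-0.03, 0.15, lower) and mitochondrial (0.06, -0.05, lower). The median with dim genes at their bound differed in sign from the plain one for SWEET on day 2 (-0.02 and 0.06).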
